A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

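The deposited values are a coverage signal made by the authors: reads per nucleotide of each feature, 1 column per library for 16 libraries, with 8 further columns equal to the mean of the 2 libraries of a group (largest difference 5.2e-12) that were not used. Per the submitters' processing notes the tools were Trim Galore, HISAT2 2.2.0, featureCounts 2.0.0 and DESeq2 with genome build R64; their order and roles are not given in the sources used here. Per the labels, RNA was extracted with hot phenol, 1 µg of total RNA received a fixed amount of ERCC spike-in, ribosomal RNA was depleted and stranded libraries were made. The scaling between libraries is not stated in the labels; the values fit a scaling to the spike-ins, since scaling to them again gave factors of 1.00 in all libraries.

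Of 12089 features, 92 are spike-ins (58 detected in every library), and 11606 of the other 11997 had a mean at or above the pseudocount of 0.00364, the 5th percentile of positive values, and were tested. These included 5817 of 5899 protein-coding genes, 1624 of 1664 XUTs, 830 of 847 SUTs, 904 of 925 CUTs and 1434 of 1526 NUTs. Reads were recovered from the step between values times the ORF length on 5623 single-exon ORFs. Whole numbers were checked on the 329 to 736 ORFs per library with a low recovered count. Of these, 49.7 to 80.1% gave a whole number within 0.02, so no count test was run. One read-based scale helps to read low values: the pseudocount equals 3.29 to 13.8 reads per kb. The lncRNA features come without coordinates, so overlaps with genes on the same strand could not be removed. As a check chosen after the data were seen, lncRNAs whose ratio to 1 mRNA had a log2 SD under 0.05 over all libraries were sought: 62 of 1826 lncRNAs at a level of 0.05 or more did, all NUTs, against 28 of 5513 mRNAs. A limit of 0.1 was tried first and lowered after it took in 1573 mRNAs.

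log2(value + 0.00364) was fitted with limma (lmFit, contrasts.fit and eBayes with a trend) with 1 mean per group over all 16 libraries (8 residual degrees of freedom, prior degrees of freedom 4.43). Features with a Benjamini-Hochberg adjusted p under 0.05 within a comparison passed; log2 changes are given ± SE. There were 10 planned comparisons, 3 of them interactions; 4 more (starvation under cycloheximide, each deletion in starvation, xrn1 against upf1) were chosen after the data were seen. The comparisons, 22 gene lists, 9 transcript classes, the rule for named genes and the alternatives were fixed before the data were examined. The lists hold 755 symbols, of which 753 matched: cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, glycolysis, gluconeogenesis and glyoxylate cycle, glucose-repressed sugar use, hexose transporters, TCA cycle and respiratory chain, trehalose and glycogen, stress response and chaperones, amino acid biosynthesis, nitrogen catabolite repression, known targets of nonsense-mediated decay, mRNA decay machinery, proteasome, histones, cell cycle, phosphate starvation, meiosis and sporulation, and genes specific to mating type a or alpha. They were tested with camera, which compares a list with all other tested features, so its direction can differ from that of a median relative to protein-coding genes. The preset correlation was 0.01, and the estimated one was 0.54 for protein-coding genes and 0.0782 for XUTs.

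Named features were, in 5 comparisons (starvation in wild type, cycloheximide in glucose and in starvation, and each deletion in glucose), the 6 protein-coding genes and 4 lncRNAs with the largest rise and with the largest fall among those passing, with both libraries of one group above both of the other. In the other comparisons they were the 3 and 2 largest each way, and for each list up to 2 members. Dubious and transposon ORFs and the deleted or auxotrophic loci were left out. The alternatives were a pseudocount 10 times larger or smaller, no filter or one 10 times stricter, scaling by median of ratios over protein-coding genes, snoRNAs or spike-ins, a fit of the compared groups alone, the replicate number as a block, a 2-fold minimum, an estimated correlation and leaving out each library. A fit without the 4 cycloheximide libraries was chosen after the data were seen.

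Changes were added to simulated data with the observed spread of each feature to measure recovery among 11606 features. The noise was drawn independently for each feature, and few features were changed. In the data protein-coding genes were correlated (0.54) and far more features passed, so the rates may not hold there. For starvation in wild type 29.9%, 65.7% and 75.8% of 67, 67 and 66 changed features passed at log2 changes of 0.6, 1 and 2, with 7 false calls of 121. For upf1 34.3%, 71.6% and 89.4% passed, with 4 false calls of 134. The variance between replicates was 2.62 to 5.82 times that of counting error (chi-square per degree of freedom). It was taken over the 438 to 555 ORFs per group with whole recovered reads in both libraries. Replicates correlated at 0.977 to 0.991 across features on the log2 scale, and shared no identical ORF values among those compared. R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.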

Results

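Strand-specific total RNA sequencing was carried out on 16 libraries of haploid Saccharomyces cerevisiae, in 8 groups of 2 libraries that the series' design text calls biological replicates. Wild-type cells, cells without Upf1 (the RNA helicase at the centre of nonsense-mediated decay) and cells without Xrn1 (the cytoplasmic 5'-3' exonuclease) were grown in glucose and then kept for 16 min either in glucose or in medium with glycerol and ethanol, here called starvation. Wild-type cells then received cycloheximide, an inhibitor of translation elongation, at 100 µg/ml, or the solvent DMSO. The labels name no solvent for the mutants and no exposure time for the drug. The deposited values are reads per nucleotide for 11997 features other than spike-ins: mRNAs, tRNAs, snoRNAs and 4 families of long noncoding RNA (lncRNA). XUTs were defined elsewhere by their accumulation without Xrn1, and CUTs are cryptic unstable transcripts degraded by the nuclear exosome. SUTs are stable unannotated transcripts, and NUTs are Nrd1-unterminated transcripts. Depth was recovered from the steps between values, in units of 1e6 reads (M). It ranged from 6.72 M to 33.1 M reads on open reading frames (ORFs) per library. The group with the fewest was starved wild type with cycloheximide (6.72 M to 8.40 M), and that with the most was starved xrn1 (26.9 M to 33.1 M). The median ORF held 506 to 2650 reads. In every library the spike-in RNAs summed to 305 to 317, so levels are relative to a fixed amount of spike-in per µg of total RNA, most of which is ribosomal, and not per cell.

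The deleted genes were examined first. In glucose, UPF1 (YMR080C) lay at 0.599 ± 0.0235 reads per nucleotide (SD, n = 2) in wild type and at 0.0147 ± 0.000746 in upf1, and in starvation at 0.329 ± 0.00906 and 0.00933 ± 3.47e-05. XRN1 (YGL173C) lay at 1.16 ± 0.0343 in wild type and 0.0775 ± 0.0117 in xrn1 in glucose, and at 0.716 ± 0.0329 and 0.0798 ± 0.00638 in starvation. In xrn1 the UPF1 mRNA stood at 2.47 ± 0.185 in glucose. MET15 was listed at 0 in all 16 libraries, and the group means of LEU2 and URA3 did not exceed 0.00121 and 0.00715. HIS3, whose allele in these strains is a partial deletion, lay between 0.272 and 2.2 in the group means. The mRNAs made only by mating type a cells were present (in wild type in glucose MFA1 at 2.54 and STE2, the alpha-factor receptor, at 2.72), while the pheromone genes of alpha cells, MF(ALPHA)1 and MF(ALPHA)2, had group means of at most 0.0228 and 0.0278. Other alpha-specific genes were not as low: STE3, AFB1 and SAG1 had group means up to 0.219, 0.478 and 1.35. In wild type in glucose SAG1 stood at 0.113, above ASG7, which is specific to mating type a (0.102).

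Across the protein-coding genes the library medians averaged 0.223 ± 0.00660 reads per nucleotide (SD, n = 2) in wild type in glucose, 0.176 ± 0.00680 in starvation, 1.02 ± 0.0990 with cycloheximide in glucose, 0.447 ± 0.0310 with cycloheximide in starvation, 0.237 ± 0.0330 in upf1, 0.161 ± 0.00540 in starved upf1, 1.05 ± 0.0720 in xrn1 and 1.06 ± 0.0270 in starved xrn1. The XUT medians in the same order were 0.0108, 0.00969, 0.0584, 0.0238, 0.0269, 0.0184, 0.0806 and 0.0868. The snoRNA medians stayed between 6.88 and 11.5, the highest being starved upf1, whose libraries stood at 8.31 and 14.8. Scaling to protein-coding genes shifted the median change of all features by -1.84 for cycloheximide in glucose, -1.05 for cycloheximide in starvation, -1.88 for xrn1, 0.284 for starvation in wild type and 0.507 for starvation in upf1. Scaling to snoRNAs shifted it by 0.293, 0.220, 0.0584, 0.314 and -0.130 in the same order.

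**Figure D1:**
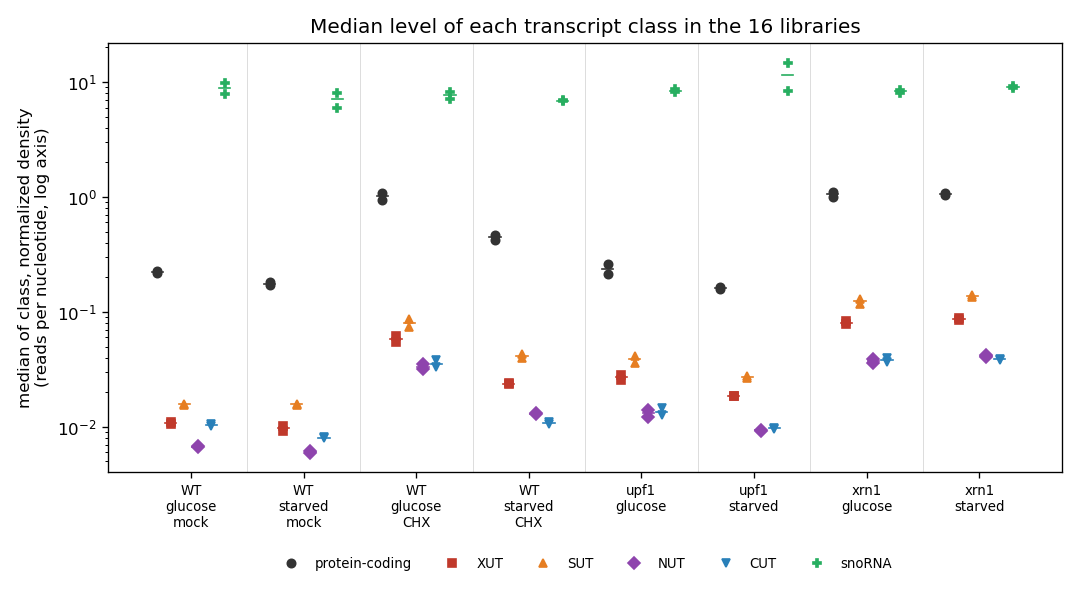
Median level of each transcript class (reads per nucleotide, log axis) in each of the 16 libraries, by group; points are libraries and short lines group means. Protein-coding medians are near 0.223 in wild type in glucose and near 1.02 and 1.05 with cycloheximide and in xrn1, while snoRNA medians stay between 6 and 14.8.

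The first comparison asked what changed in wild-type cells within 16 min of the loss of glucose. Many mRNAs for the use of other carbon sources, for storage carbohydrates and for stress responses rose, and most for ribosomes and their assembly fell. No list call by camera held with an estimated correlation. ISF1 (YMR081C, chromosome XIII, 430079 to 431095 in R64), a glucose-repressed gene, rose from 0.0155 ± 0.00114 to 1.24 ± 0.114 reads per nucleotide (SD, n = 2), a log2 change of 6.02 ± 0.22 (SE, limma adjusted p = 2.3e-09). RGI2, a gene induced during respiratory growth, changed by 5.78 ± 0.40, and HXT6, a high-affinity glucose transporter gene, by 5.22 ± 0.14 (from 0.0529 ± 0.00404 to 2.11 ± 0.265). HXT6 and its neighbour HXT7 are near-identical, so their shares of reads are uncertain. GAC1, which encodes a phosphatase subunit that promotes glycogen synthesis, rose by 4.89 ± 0.21, ADY2, an acetate transporter gene, by 4.86 ± 0.18, and the small ORF YPR159C-A by 4.82 ± 0.67.

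Among the falls, FAR1, an inhibitor of the cyclin-dependent kinase in the pheromone response, went from 0.401 ± 0.00762 to 0.0637 ± 2.68e-04 (-2.59 ± 0.12), and CLB2, a mitotic cyclin gene, from 0.312 ± 0.00588 to 0.0534 ± 0.00541 (-2.47 ± 0.16). The uncharacterised YGR079W changed by -2.58 ± 0.11, YBR032W by -2.82 ± 0.36 and SFG1, linked to filamentous growth, by -2.25 ± 0.17. YLR264C-A, at 0.0283 in glucose, was listed at 0 in both starved libraries. Of the lncRNAs, SUT068 (4.31 ± 0.22), SUT303 (3.90 ± 0.24), NUT1072 (3.43 ± 0.20) and XUT1142 (3.31 ± 0.15) rose most, and CUT538 (-3.13 ± 0.81), CUT627 (-3.08 ± 0.46) and CUT070 (-2.60 ± 0.37) fell most. SUT741 was listed at 0 in starvation against 0.0260 in glucose.

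Lists of genes fixed beforehand moved as follows, with medians given relative to the protein-coding median of -0.42. Of the 20 trehalose and glycogen genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone), with a relative median of 1.90. Examples were GAC1 and the glycogen synthase gene GSY1 (4.02 ± 0.17). The 22 genes of glucose-repressed sugar use had 16 rises and 2 falls (16 and 2 adjusted over the list alone, relative median 1.5), led by MTH1, a regulator of hexose transporter genes (3.49 ± 0.14), and the maltose permease gene MAL11 (3.02 ± 0.16). Among 46 stress and chaperone genes 31 rose and 6 fell (31 and 6 adjusted over the list alone, 1.42), with USV1, a transcription factor gene, at 3.55 ± 0.17 and the Hsp70 gene SSA4 at 3.51 ± 0.17. Among 22 gluconeogenesis and glyoxylate genes 14 rose and 2 fell (14 and 2 adjusted over the list alone, 1.41), with the lactate and pyruvate permease gene JEN1 at 4.39 ± 0.14. Of 14 hexose transporter genes 7 rose and 0 fell (7 and 0 adjusted over the list alone, 1.00), with HXT4 at 3.56 ± 0.15. The adjusted p of these 5 lists (camera, preset correlation) was 6.97e-15, 2.82e-14, 5.15e-18, 7.95e-12 and 5.48e-08 in that order. None held with an estimated correlation: adjusted p = 0.282, 0.269, 0.282, 0.282 and 0.235 with an estimated correlation.

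On the other side, 136 of the 137 cytosolic ribosomal protein genes fell and 0 rose (0 and 136 adjusted over the list alone, relative median -0.57), RPS28B by -1.86 ± 0.10 and RPL14B by -1.48 ± 0.09. Ribosome biogenesis genes fell in 79 of 80 cases (0 and 80 adjusted over the list alone, -0.69), including the RNA polymerase I subunit genes RPA12 (-2.10 ± 0.14) and RPA34 (-1.82 ± 0.12). Translation factor genes fell in 37 of 38 (0 and 37 adjusted over the list alone, -0.47), including SUI1, which encodes eIF1 (-1.45 ± 0.08). Amino acid biosynthesis genes fell in 45 of 48 cases (1 and 45 adjusted over the list alone, -0.29, ILV5 -1.78 ± 0.11). Cell cycle genes fell in 20 of 25 (0 and 20 adjusted over the list alone, -0.30, CLB2 and the polo kinase gene CDC5, -1.66 ± 0.14), histone genes in 10 of 10 (0 and 10 adjusted over the list alone, -0.22), mRNA decay genes in 26 of 35 with 2 rises (2 and 28 adjusted over the list alone, -0.14, EDC2 0.93 ± 0.11) and genes specific to mating type a in 6 of 7 (0 and 7 adjusted over the list alone, -0.62, STE2 -1.81 ± 0.10). The camera adjusted p was 3.29e-32, 5.81e-23, 3.09e-11, 2.06e-09, 6.94e-05, 0.00183, 0.00226 and 0.00110 in this order. These were adjusted p = 0.282, 0.282, 0.348, 0.5, 0.5, 0.5, 0.721 and 0.282 with an estimated correlation, so no call held. Scaled to snoRNAs, falls in these 8 lists numbered 82, 48, 7, 8, 6, 0, 0 and 3. The medians of histone and mRNA decay genes stayed below 0, at -0.24 and -0.16, and were -0.28 and -0.20 scaled to protein-coding genes (7 and 18 falls).

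The other 9 lists did not pass the camera test. Glycolysis genes had 2 rises and 12 falls of 16 (2 and 12 adjusted over the list alone, PGI1 -0.80 ± 0.10), phosphate starvation genes 1 and 9 of 14 (1 and 9 adjusted over the list alone, PHO84 -1.32 ± 0.14), and genes of mating type alpha 0 and 1 of 5 (0 and 1 adjusted over the list alone, SAG1 -0.60 ± 0.16). The remaining 6 had medians below 0 as deposited and above 0 when libraries were scaled to protein-coding genes or to snoRNAs: mitochondrial ribosomal proteins (2 rises and 28 falls of 67, 2 and 28 adjusted over the list alone), proteasome (2 and 20 of 34, 2 and 23 adjusted over the list alone, its regulator RPN4 1.36 ± 0.11), known targets of nonsense-mediated decay (1 and 6 of 13, 1 and 6 adjusted over the list alone), nitrogen catabolite repression (6 and 8 of 24, 6 and 8 adjusted over the list alone, the proline permease gene PUT4 2.32 ± 0.20), the TCA cycle and respiratory chain (8 and 17 of 54, 8 and 17 adjusted over the list alone, CYB2 2.97 ± 0.20) and meiosis (3 and 2 of 20, 3 and 1 adjusted over the list alone). For the last 3 the camera direction was up while the median lay below 0, at -0.24, -0.13 and -0.09. The means of nitrogen catabolite repression and of the TCA cycle and respiratory chain lay just above 0 (0.01 for the latter), and that of meiosis at -0.04.

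Over all 11606 features tested, 5047 passed in starved wild type, 1162 up and 3885 down. Scaled to protein-coding genes the split was 2879 up and 2707 down, and scaled to snoRNAs 1316 up and 624 down. Of the 1624 XUTs 182 rose and 151 fell, with a median of -0.07, which is 0.35 above the protein-coding median (camera adjusted p = 3.17e-05, adjusted p = 0.527 with an estimated correlation). Of the 830 SUTs 122 rose and 106 fell (median -0.04), of the 904 CUTs 58 rose and 175 fell (-0.28), and of the 1434 NUTs 132 rose and 140 fell (-0.11). The XUT, SUT and NUT medians turned positive when libraries were scaled to protein-coding genes (0.21, 0.27 and 0.14) or to snoRNAs (0.21, 0.28 and 0.14). The direction of these classes thus rests on the scaling. Their position relative to mRNAs can hardly change with it, since scaling moves all features of a library alike apart from the pseudocount. Of 293 tRNA features, which this library type samples poorly, 1 rose and 103 fell (median -1.18).

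The next comparison asked which transcripts change when translation elongation is blocked in glucose. Nearly every mRNA and lncRNA stood higher with cycloheximide: of 5817 protein-coding genes 5745 rose and 3 fell, with a median log2 change of 2.05, and of 1624 XUTs 1514 rose and 1 fell, with a median of 2.05. XUT medians depend on the pseudocount, which is near their level: with one 10 times larger the medians of mRNAs and XUTs were 1.82 and 0.96, and with one 10 times smaller 2.09 and 2.45. SUTs (777 up, 0 down of 830, median 2.10), NUTs (1320 up, 16 down of 1434, 1.78) and CUTs (688 up, 4 down of 904, 1.44) rose as well, though CUTs turned to 92 up and 177 down (median -0.23) when scaled to protein-coding genes. Of 76 snoRNAs 4 rose and 29 fell (median -0.30, 0.03 when scaled to snoRNAs), and of 25 mitochondrially encoded features 1 rose and 11 fell (median -0.21, 0.03 when scaled to snoRNAs).

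The uncharacterised gene YHR022C rose from 0.0280 ± 0.00508 to 2.32 ± 0.268 reads per nucleotide (SD, n = 2, log2 change 6.20 ± 0.20, adjusted p = 2.07e-10), and NRG1 (YDR043C), a repressor of glucose-repressed genes, from 0.187 ± 0.0143 to 6.75 ± 0.810 (5.14 ± 0.15, adjusted p = 1.54e-10). SPO24, a small sporulation gene, reached 84.5 ± 2.32 from 3.28 ± 0.122 (4.68 ± 0.08). ZPS1, which encodes a cell wall protein regulated by zinc and pH, changed by 5.79 ± 1.12 (its replicates differed widely in the mutants), and the small ORFs YIL134C-A and YER085C by 4.65 ± 0.39 and 4.53 ± 0.51. Among lncRNAs NUT0676 (5.69 ± 1.12), XUT1187 (5.35 ± 0.58), XUT1188 (4.98 ± 0.47) and NUT1003 (4.87 ± 0.51) rose most. NUT0676 kept a ratio of 0.608 to 0.668 to ZPS1 in all 16 libraries, so this pair is not counted as separate measurements. Only 3 protein-coding genes fell: IRC13 (-0.76 ± 0.15) and the small ORFs YDR034C-A (-1.94 ± 0.82) and YCR085W (-1.76 ± 0.67). In this comparison 10685 features passed, against 10702 with an unadjusted limma p under 0.05. The adjustment thus did little, and falls with a large SE may be false calls. Among lncRNAs NUT1269 (-1.09 ± 0.28), CUT763 (-1.15 ± 0.39) and CUT523 (-1.30 ± 0.47) fell, and CUT034 was listed at 0.

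Because most mRNAs rose, lists are given relative to the protein-coding median of 2.05. They were not matched for level, with which the change also varied. Its protein-coding median was 2.25 in the fifth decile by level and 1.11 in the highest. Glycolysis genes lay lowest: 10 of 16 rose and 0 fell (10 and 0 adjusted over the list alone), with a relative median of -1.64, and with libraries scaled to protein-coding genes 0 rose and 16 fell (camera adjusted p = 4.87e-06, down, adjusted p = 0.817 with an estimated correlation). PFK1 and PFK2, the phosphofructokinase genes, changed by 0.90 ± 0.11 and 0.99 ± 0.10 as deposited and by -1.14 and -1.04 under that scaling. Cytosolic ribosomal protein genes rose in 136 of 137 cases and fell in 0 (136 and 0 adjusted over the list alone), but 128 fell and 4 rose under the protein-coding scaling (relative median -0.98, camera adjusted p = 0.0329, up, adjusted p = 0.844 with an estimated correlation). RPL22B and RPS9A stood out at 3.45 ± 0.11 and 3.23 ± 0.10. The same turn of direction held for amino acid biosynthesis (48 up and 0 down of 48 as deposited, 0 and 43 scaled to protein-coding genes), translation factors (38 and 0 of 38, then 2 and 31), the proteasome (34 and 0 of 34, then 3 and 30) and the TCA cycle and respiratory chain (54 and 0 of 54, then 4 and 40). Counts adjusted over the list alone equalled those at the deposited scale. Of these 4 lists the proteasome passed camera (adjusted p = 0.0329, up, adjusted p = 0.844 with an estimated correlation), and the other 3 did not (adjusted p = 0.252, 0.310 and 0.0503).

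Lists above the protein-coding median under every scaling included genes of mating type a (7 of 7 up, relative median 0.74, ASG7 3.66 ± 0.21, MFA1 3.48 ± 0.11), trehalose and glycogen (20 of 20, 0.68, TPS2, for trehalose synthesis, 3.20 ± 0.14), meiosis (20 of 20, 0.67, IME2 3.5 ± 0.16), cell cycle (25 of 25, 0.38, PCL9 3.29 ± 0.14), nitrogen catabolite repression (24 of 24, 0.36, DAL7 3.5 ± 0.14), known targets of nonsense-mediated decay (13 of 13, 0.30, EST2, a telomerase gene, 3.32 ± 0.16) and phosphate starvation (14 of 14, 0.29, SPL2 4.21 ± 0.18), with the same counts adjusted over the list alone. Their camera adjusted p was 0.0329, 0.0263, 0.128 (meiosis, not passing), 0.0329, 0.0329, 0.0329 and 0.0263, and adjusted p = 0.817 with an estimated correlation for each of them. Scaling moves all features of a library alike apart from the pseudocount, so the relative positions of these lists could hardly change with it. In all, 10685 of 11606 features passed, 10588 up and 97 down. Scaled to protein-coding genes the split was 3705 up and 2889 down. Both cycloheximide groups carry another prefix in their column names than the other 12 libraries, so any difference between these sets of libraries cannot be told apart from the drug in this comparison or in that in starvation.

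With cycloheximide in starvation, the rise was smaller and most mRNAs for ribosomal proteins and ribosome assembly fell. Neither list call held with an estimated correlation (camera adjusted p = 0.155 for both). OYE3 (YPL171C, chromosome XVI, 226169 to 227371), an NADPH oxidoreductase gene, rose from 0.0441 ± 0.0119 to 7.81 ± 0.442 reads per nucleotide (SD, n = 2), a log2 change of 7.38 ± 0.21 (adjusted p = 1.5e-10). FAT3, for fatty acid uptake, changed by 5.25 ± 0.18, OSI1, induced by oxidative stress, by 4.91 ± 0.21, AAD4, a putative aryl-alcohol dehydrogenase gene with near-identical relatives, by 4.88 ± 0.12, the glutathione transferase gene ECM4 by 4.83 ± 0.16 and the carnitine acetyltransferase gene CAT2 by 4.29 ± 0.15. HO, the endonuclease of mating type switching, fell from 0.483 ± 0.00416 to 0.0736 ± 0.00149 (-2.65 ± 0.13), the ribonucleotide reductase gene RNR1 changed by -2.20 ± 0.10, YEF3, which encodes a translation elongation factor, went from 17.8 ± 0.252 to 4.09 ± 0.262 (-2.12 ± 0.08). TOS6 changed by -2.09 ± 0.09 and the IMP dehydrogenase gene IMD4 by -2.06 ± 0.07. YJL052C-A was listed at 0 with the drug. Of the lncRNAs XUT0181 (4.74 ± 0.68), XUT0441 (4.18 ± 0.56), XUT0977 (4.04 ± 0.26) and XUT0172 (3.72 ± 0.21) rose most, CUT287 (-3.02 ± 0.20), CUT316 (-2.31 ± 0.41) and NUT0257 (-2.15 ± 0.33) fell most, and CUT458 was listed at 0 with the drug.

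Of 137 cytosolic ribosomal protein genes 3 rose and 128 fell (3 and 129 adjusted over the list alone), with a median of -0.87, -2.18 relative to the protein-coding median of 1.31. RPL1B changed by -1.66 ± 0.07. Of 80 ribosome biogenesis genes 7 rose and 65 fell (7 and 65 adjusted over the list alone, relative median -2.10, DBP2 -1.62 ± 0.09), and of 16 glycolysis genes 1 rose and 12 fell (1 and 12 adjusted over the list alone, -1.94, PDC1 -1.42 ± 0.08). Translation factors (10 up, 17 down of 38, 10 and 17 adjusted over the list alone, -1.49) and amino acid biosynthesis (19 and 19 of 48, 19 and 19 adjusted over the list alone, -1.44) had medians of -0.18 and -0.13, which turned to 0.04 and 0.08 when scaled to snoRNAs. The mean of the amino acid list was already above 0, at 0.10. Scaled to snoRNAs, falls in these 5 lists numbered 100, 48, 8, 12 and 8. Lists were not matched for level, and the protein-coding median change was 1.5 in the fifth decile by level and -0.16 in the highest. The camera adjusted p of these 5 lists was 1.17e-83, 2.25e-44, 7.93e-12, 1.26e-12 and 1.96e-07. The values became adjusted p = 0.155, 0.155, 0.401, 0.611 and 0.611 with an estimated correlation.

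Lists above the protein-coding median included gluconeogenesis and the glyoxylate cycle (22 of 22 up, 0 down, 1.19, CAT2, and the alcohol dehydrogenase gene ADH2 at 4.09 ± 0.15), glucose-repressed sugar use (21 of 22, 0.76, REG2 3.44 ± 0.23), nitrogen catabolite repression (24 of 24, 0.69, the amino acid permease gene GAP1 4.06 ± 0.15), the TCA cycle and respiratory chain (54 of 54, 0.55, NDE2 3.74 ± 0.20), trehalose and glycogen (19 of 20, 1 down, 0.70), histones (10 of 10, 0.47, HHF1 2.13 ± 0.11) and mitochondrial ribosomal proteins (67 of 67, 0.30, MRPL4 2.64 ± 0.16), each with the same count adjusted over the list alone. Their camera adjusted p was 1.77e-05, 2.89e-04, 1.75e-04, 5.98e-08, 0.00245, 0.00298 and 2.21e-07, and with an estimated correlation adjusted p = 0.658 for trehalose and glycogen and 0.611 for each other list. In total 8599 features passed, 7634 up and 965 down (3589 up and 3655 down when scaled to protein-coding genes). Of 1624 XUTs 1007 rose and 55 fell (median 1.01, or 0.36 and 1.28 with the larger and smaller pseudocount), of 830 SUTs 618 rose and 24 fell (1.19), and of 904 CUTs 233 rose and 97 fell (0.18, or -0.68 when scaled to protein-coding genes). Of 25 mitochondrially encoded features 0 rose and 24 fell (median -0.98).

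The difference between these drug effects was tested as an interaction. Relative to its effect in glucose, cycloheximide in starvation left 7069 features lower and 239 higher (7308 passed). The split was 2788 lower and 1961 higher when libraries were scaled to protein-coding genes. The protein-coding median of the interaction was -0.80 and the XUT median -1.03, or -0.76 and -0.51 with a pseudocount 10 times larger. All 137 ribosomal protein genes and all 80 ribosome biogenesis genes had a lower drug effect in starvation (the same counts adjusted over the list alone), with relative medians of -1.19 and -1.89. RPS9A differed by -3.45 ± 0.14 and SSF1, a ribosome assembly factor gene, by -3.64 ± 0.18 (camera adjusted p = 1.8e-36 and 6.88e-29, adjusted p = 0.299 with an estimated correlation for both). The TCA cycle and respiratory chain list had 12 members higher and 2 lower of 54 (8 and 1 adjusted over the list alone, relative median 1.05, camera adjusted p = 5.92e-27, up, adjusted p = 0.299 with an estimated correlation), with NDE2 at 1.72 ± 0.28. Of these 54, 53 were higher when scaled to protein-coding genes. Scaled to snoRNAs, 3 were higher and 0 lower (median 0.14). The largest single differences were OYE3 (6.08 ± 0.29), YLR154C-H (5.03 ± 1.00, a small ORF near the ribosomal DNA, with near-identical copies) and RGI2 (3.22 ± 0.57) upward, and PCL1, a cyclin gene (-4.39 ± 0.22), YMR230W-A (-4.28 ± 0.39) and YMR141C (-4.26 ± 0.56) downward. Among lncRNAs they were SUT220 (3.21 ± 0.31) and CUT876 (3.07 ± 1.10), and CUT480 (-4.88 ± 0.23) and XUT0182 (-4.86 ± 0.70). Starvation in the presence of the drug, a comparison added after the data were seen, gave 811 features up and 8555 down. RGI2 changed by 9.01 ± 0.40 there, OYE3 by 7.47 ± 0.21, YGR079W by -6.71 ± 0.11 and PCL1 by -5.50 ± 0.15.

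Loss of Upf1 in glucose was compared with wild type to find RNAs sensitive to nonsense-mediated decay. XUTs and SUTs mostly rose while the protein-coding median lay near 0. Of 1624 XUTs 1011 rose and 3 fell, with a median log2 change of 1.08 (0.39 with a pseudocount 10 times larger and 1.40 with one 10 times smaller), and of 830 SUTs 565 rose and 1 fell (median 1.13). Of 1434 NUTs 619 rose and 13 fell (0.54) and of 904 CUTs 175 rose and 15 fell (0.20). Of 5817 protein-coding genes 1206 rose and 1073 fell, with a median of -0.08. Camera with a preset correlation gave adjusted p = 2.86e-18 for XUTs and 9.97e-20 for SUTs. These became adjusted p = 0.101 and 0.122 with an estimated correlation. Known targets of nonsense-mediated decay also moved up: 11 of 13 rose and 0 fell (11 and 0 adjusted over the list alone), with a median 0.77 above the protein-coding one (camera adjusted p = 4.63e-04, adjusted p = 0.496 with an estimated correlation), led by STN1 (2.29 ± 0.12) and TEN1 (1.82 ± 0.16), which cap telomeres.

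DAL7, a malate synthase gene of allantoin breakdown, rose from 0.0890 ± 0.00925 to 0.793 ± 0.128 reads per nucleotide (SD, n = 2, 3.10 ± 0.14, adjusted p = 1.69e-08), COS12 by 3.18 ± 0.17, and the uncharacterised YGL262W and YNL018C by 3.56 ± 0.35 and 3.59 ± 0.34. AAD15, a member of the aryl-alcohol dehydrogenase family whose reads are uncertain, was listed at 0 in wild type and stood at 0.0654 ± 0.0175 in upf1. ZPS1 changed by 4.14 ± 1.12, with 1.79 ± 2.12 in upf1, a spread as large as the mean. The same holds for NUT0676 (4.05 ± 1.12), which tracks it, and the spread was wide for XUT1361 (4.47 ± 0.65, 0.378 ± 0.313) and XUT1187 (3.70 ± 0.58). XUT0487 was listed at 0 in wild type and stood at 0.0391 ± 0.00319 in upf1. The largest falls were in PHO84, the high-affinity phosphate transporter gene, from 1.54 ± 0.277 to 0.112 ± 0.0227 (-3.74 ± 0.14, adjusted p = 1.19e-08), SPL2 (-2.71 ± 0.18), PHO89, another phosphate transporter gene (-2.38 ± 0.15), YLR154C-H (-2.04 ± 0.71), PHM6 (-1.81 ± 0.25) and the a-factor gene MFA1 (-1.24 ± 0.11). Among lncRNAs CUT788 (-1.68 ± 0.53), CUT675 (-1.43 ± 0.49) and XUT0649 (-1.27 ± 0.48) fell, and CUT625 was listed at 0 in upf1.

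Of the 14 phosphate starvation genes 1 rose and 10 fell (1 and 11 adjusted over the list alone, relative median -0.57), of 80 ribosome biogenesis genes 1 rose and 72 fell (1 and 73 adjusted over the list alone, -0.55, NOP4 -0.95 ± 0.12). Of 137 cytosolic ribosomal protein genes 2 rose and 112 fell (3 and 118 adjusted over the list alone, -0.20, RPL22B 1.12 ± 0.11, RPL33B -0.45 ± 0.08), of 10 histone genes 0 rose and 9 fell (0 and 9 adjusted over the list alone, -0.37, HTB1 -0.70 ± 0.10). Of 7 genes of mating type a 0 rose and 6 fell (0 and 6 adjusted over the list alone, -0.56). The camera adjusted p was 2.65e-08, 1.83e-30, 1.73e-22, 5.12e-06 and 1.5e-05 (down). They were adjusted p = 0.438, 0.438, 0.496, 0.496 and 0.438 with an estimated correlation. Meiosis genes rose in 10 of 20 cases and fell in 0 (10 and 0 adjusted over the list alone, 0.91, the kinase gene IME2 2.26 ± 0.16, camera adjusted p = 0.0111, adjusted p = 0.496 with an estimated correlation). Nitrogen catabolite repression genes rose in 10 of 24 (10 and 0 adjusted over the list alone, DAL2 2.85 ± 0.14, camera adjusted p = 0.0742), and gluconeogenesis genes in 9 of 22, with 2 falls (9 and 2 adjusted over the list alone, CRC1 1.96 ± 0.17, PCK1 1.93 ± 0.16, camera adjusted p = 0.258). In total 4873 features passed, 3717 up and 1156 down. The split was 3952 up and 2797 down when scaled to protein-coding genes, and 3226 up and 115 down when scaled to snoRNAs, which also moved the protein-coding median to 0.01. Falls in the lists for phosphate starvation, ribosome biogenesis, ribosomal proteins, histones and mating type a then numbered 7, 26, 0, 1 and 4. The medians of ribosomal protein and histone genes stayed below 0, at -0.19 and -0.36 against -0.28 and -0.45 as deposited, and 125 and 10 fell scaled to protein-coding genes. The falls also varied with the libraries: features down numbered 2011 without replicate 1 of upf1 and 460 without its replicate 2, and 696 and 473 without replicate 1 and 2 of wild type.

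Loss of Xrn1 in glucose raised nearly every mRNA and lncRNA. Of 5817 protein-coding genes 5677 rose and 14 fell (median 2.06), and of 1624 XUTs 1574 rose and 0 fell (median 2.54), a class that was defined by this sensitivity and so is not independent evidence of it. With a pseudocount 10 times larger the XUT median lay below that of mRNAs (1.28 against 1.84), and with one 10 times smaller it was 2.99. SUTs had a median of 2.62 (791 up, 1 down of 830), NUTs of 1.86 (1294 up, 9 down of 1434) and CUTs of 1.43 (661 up, 7 down of 904, -0.24 when scaled to protein-coding genes). Of 76 snoRNAs 10 rose and 9 fell (median -0.05, 0.03 when scaled to snoRNAs). SRL3 (YKR091W, chromosome XI, 611525 to 612265) rose from 0.0957 ± 0.0178 to 3.80 ± 0.439 reads per nucleotide (SD, n = 2, 5.27 ± 0.15, adjusted p = 2.76e-11), MCH2 by 5.17 ± 0.21, COX26, a subunit gene of cytochrome c oxidase, by 5.16 ± 0.21, MAL11 by 5.11 ± 0.16 and GAC1 by 5.10 ± 0.21. MAL11 and MAL31 encode near-identical permeases. AAD15, listed at 0 in wild type, stood at 0.135 ± 0.00469. Among lncRNAs XUT0589 (5.61 ± 0.17), SUT228 (5.60 ± 0.13, from 0.132 ± 0.00614 to 6.61 ± 0.396), XUT1361 (5.59 ± 0.65) and SUT238 (5.46 ± 0.16) rose most. The 14 protein-coding genes that fell included HO, from 0.723 ± 0.0545 to 0.175 ± 0.0179 (-2.02 ± 0.13), PHO84 (-1.24 ± 0.14), YMR244W (-1.03 ± 0.25), and YLR154C-G (-1.95 ± 0.28) and YLR154C-H (-1.88 ± 0.71) near the ribosomal DNA. YBR221W-A was listed at 0 in xrn1. CUT538 (-2.39 ± 0.81), CUT625 (-1.59 ± 0.54), CUT542 (-0.86 ± 0.21) and SUT503 (-0.77 ± 0.20) fell. Here too the adjustment did little (10562 features passed, 10586 had an unadjusted limma p under 0.05), so falls with a large SE may be false calls.

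Relative to the protein-coding median, lists lay as far apart as -1.64 for glycolysis (10 of 16 up, 2 down, 10 and 2 adjusted over the list alone, 0 up and 16 down when scaled to protein-coding genes, GPM1 1.09 ± 0.10, or -0.98 under that scaling) and 0.66 for trehalose and glycogen (20 of 20 up, GLG1 4.71 ± 0.16). Cytosolic ribosomal protein genes all rose (137 of 137, RPS27A 3.15 ± 0.08), yet 130 fell and 5 rose when scaled to protein-coding genes (relative median -1.17). The same reversal held for translation factors (36 of 38 up, then 37 down, -0.94), amino acid biosynthesis (48 of 48 up, then 40 down, -0.89), ribosome biogenesis (80 of 80 up, then 72 down, -0.78) and phosphate starvation (10 up and 2 down of 14, then 1 and 13, -1.39). Above the median under every scaling were, among others, mitochondrial ribosomal proteins (67 of 67 up, 0.35, MRP49 4.11 ± 0.13), the TCA cycle and respiratory chain (54 of 54, 0.24, CYC7 4.07 ± 0.18), cell cycle genes (25 of 25, 0.32, ASH1 3.66 ± 0.11) and known targets of nonsense-mediated decay (13 of 13, 0.39, STN1 3.69 ± 0.12). Counts adjusted over the list alone were the same in each of these lists. Scaling moves all features of a library alike apart from the pseudocount, so positions relative to the median could hardly change with it. The lists were not matched for level, with which the change also varied. Its protein-coding median was 2.26 in the fifth decile by level and 1.07 in the highest. The camera adjusted p was 2.39e-07 for glycolysis, 2.71e-04 for phosphate starvation, 1.5e-04 for mitochondrial ribosomal proteins, 0.00309 for the TCA cycle and respiratory chain, 0.0216 for trehalose and glycogen, 0.0246 for the cell cycle and 0.0216 for decay targets. These were adjusted p = 0.909 with an estimated correlation for each. Cytosolic ribosomal proteins, ribosome biogenesis, translation factors and amino acid biosynthesis did not pass (adjusted p = 0.586, 0.394, 0.355 and 0.466). In total 10562 features passed, 10506 up and 56 down. The split was 4315 up and 2902 down when scaled to protein-coding genes. Set directly against upf1 in glucose, a comparison added after the data were seen, xrn1 was higher at 10030 features and lower at 60. TKL2, a transketolase gene, differed by 5.16 ± 0.18 and the oligopeptide transporter gene OPT2 by -2.18 ± 0.14.

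**Figure D2:**
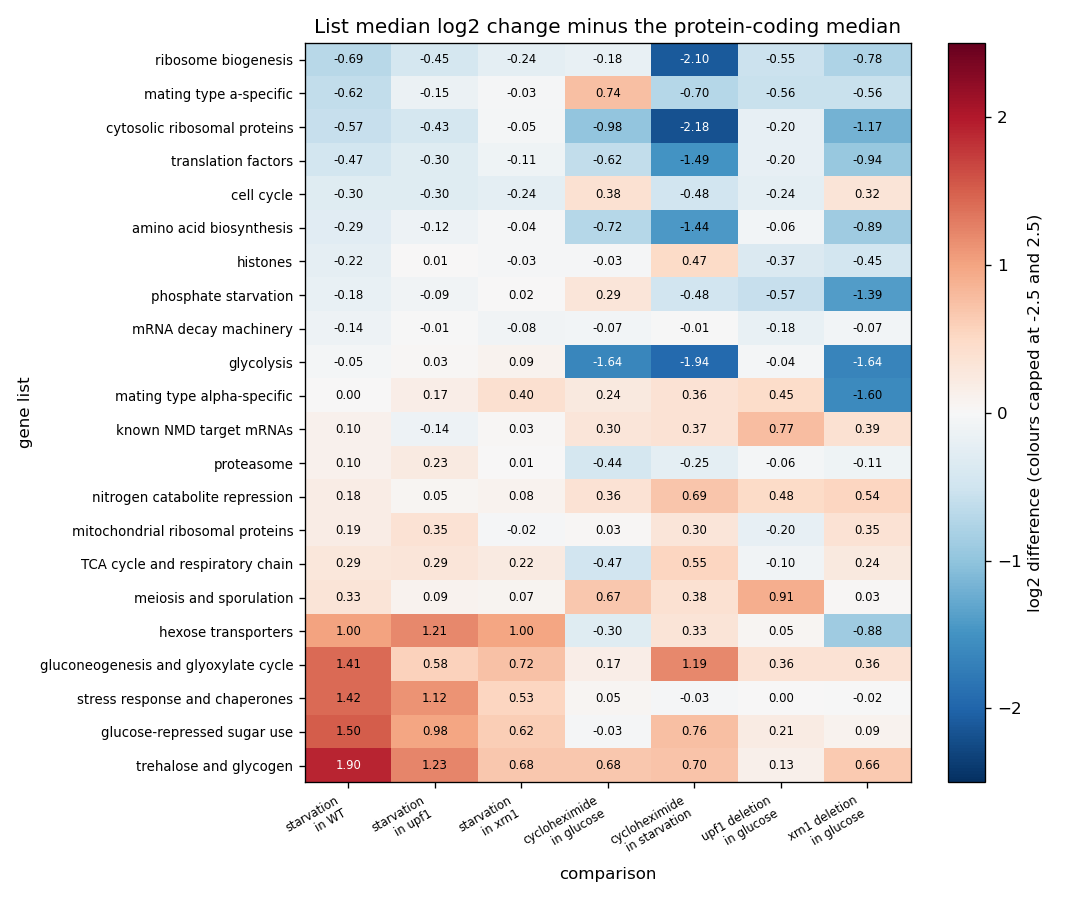
Median log2 change of each fixed gene list minus the protein-coding median, for 7 comparisons; red is above and blue below, with colours capped at -2.5 and 2.5. Trehalose and glycogen lies at 1.90 in starved wild type, and cytosolic ribosomal proteins at -2.18 with cycloheximide in starvation.

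Starvation was then examined in the mutants. In upf1 the largest changes were again in ISF1 (5.57 ± 0.22), RGI2 (5.02 ± 0.40) and ADY2 (4.43 ± 0.18) upward and in YBR032W (-3.09 ± 0.36) and YGR079W (-2.41 ± 0.11) downward, with YLR264C-A listed at 0 in starved upf1. CUT006 (3.31 ± 0.28) and NUT1244 (3.14 ± 0.33) rose and CUT716 (-3.01 ± 0.36) and CUT314 (-2.89 ± 0.39) fell. Trehalose and glycogen genes had 13 rises and 3 falls (13 and 3 adjusted over the list alone, relative median 1.23), stress and chaperone genes 29 and 9 of 46 (31 and 9 adjusted over the list alone, 1.12, HSP42 3.15 ± 0.15), and hexose transporters 8 and 1 of 14 (8 and 1 adjusted over the list alone, 1.21, HXT6 4.04 ± 0.14). Cytosolic ribosomal protein genes had 0 rises and 134 falls (0 and 135 adjusted over the list alone, -0.43, RPS28B -2.36 ± 0.10). The camera adjusted p of these lists was 1.05e-17, 9.82e-30, 2.25e-13 and 2.82e-26. The values became adjusted p = 0.270, 0.270, 0.0465 and 0.354 with an estimated correlation, so the call on hexose transporters held. In total 6389 features passed, 498 up and 5891 down (2083 up and 2045 down when scaled to protein-coding genes). Of 1624 XUTs 32 rose and 564 fell (median -0.52, or -0.04 when scaled to protein-coding genes and -0.22 with a pseudocount 10 times larger). Of 5817 protein-coding genes 322 rose and 4027 fell (median -0.61).

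In xrn1, 325 features rose and 27 fell with starvation, 352 in all. The count was 1049 (800 up, 249 down) when the fit held the compared groups alone, 554 with a replicate block and 561 with a pseudocount 10 times larger. It was 999 when scaled to protein-coding genes (699 up, 300 down) and 122 when scaled to snoRNAs. Without replicate 1 or 2 of xrn1 in glucose it was 198 or 139, and without those of starved xrn1 152 or 146. HXT13, a hexose transporter family gene, rose from 0.00240 ± 1.33e-04 to 0.247 ± 0.00652 reads per nucleotide (SD, n = 2, 5.37 ± 0.32, adjusted p = 4.7e-07), RGI2 by 5.25 ± 0.40 and the glycerol symporter gene STL1 from 0.0535 ± 0.00210 to 1.71 ± 0.0208 (4.91 ± 0.18). ADF1 (-0.75 ± 0.16), the ribosome biogenesis gene RRP17 (-0.59 ± 0.13) and the cell cycle repressor gene YOX1 (-0.59 ± 0.12) fell. SUT303 (3.07 ± 0.24) and CUT772 (2.59 ± 0.45) rose, and SUT563 (-2.24 ± 0.49) and CUT188 (-1.35 ± 0.29) fell. Rises were found in the lists for growth without glucose: hexose transporters (9 of 14 up, 9 and 0 adjusted over the list alone, HXT6 2.68 ± 0.14), gluconeogenesis and glyoxylate (12 of 22, 16 and 0 adjusted over the list alone, ADY2 4.67 ± 0.18), glucose-repressed sugar use (10 of 22, 12 and 0 adjusted over the list alone, CAT8 2.04 ± 0.16), trehalose and glycogen (11 of 20, 17 and 0 adjusted over the list alone, GAC1 1.90 ± 0.21) and stress (23 of 46, 30 and 0 adjusted over the list alone, SIP18 1.97 ± 0.22), with no member of these lists down. Scaled to snoRNAs, 6, 7, 4, 4 and 6 members rose in this order. Their camera adjusted p was 2.5e-19, 8.48e-25, 2.79e-14, 2.75e-19 and 5.01e-22. These became adjusted p = 0.0136, 0.0887, 0.182, 0.235 and 0.275 with an estimated correlation, so the call on hexose transporters held. Of 137 cytosolic ribosomal protein genes 0 rose and 1 fell (0 and 0 adjusted over the list alone), and the 80 ribosome biogenesis genes had a relative median of -0.24 (camera adjusted p = 6.52e-23, adjusted p = 0.249 with an estimated correlation).

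Whether the starvation response differed from wild type was tested as an interaction. The labels name DMSO, added after the shift, for wild type and not for the mutants. An effect of this step on the starvation response cannot be told apart from that of either deletion. Without Xrn1, 2358 features had a higher and 393 a lower response (2751 in all). This split turned with the scaling, to 1499 higher and 1596 lower when scaled to protein-coding genes and to 21 higher and 275 lower when scaled to snoRNAs. Without replicate 2 of xrn1 in glucose 1661 features passed. Relative to the protein-coding median of 0.40 (-0.13 when scaled to snoRNAs), ribosomal protein genes differed by 0.51 (134 of 137 higher, 0 lower, 136 and 0 adjusted over the list alone, RPS28B 2.07 ± 0.14) and ribosome biogenesis genes by 0.47 (71 of 80, 74 and 0 adjusted over the list alone, RPA12 1.88 ± 0.20). Trehalose and glycogen genes differed by -1.03 (2 higher and 10 lower of 20, 2 and 11 adjusted over the list alone), glucose-repressed sugar use by -0.94 (1 and 9 of 22, 1 and 9 adjusted over the list alone, MAL11 -2.61 ± 0.23) and stress genes by -0.85 (6 and 20 of 46, 8 and 24 adjusted over the list alone, SSA4 -2.68 ± 0.23). The camera adjusted p was 6.48e-42, 2.69e-21, 5.43e-11, 3.95e-11 and 1.53e-13. They were adjusted p = 0.398, 0.398, 0.466, 0.398 and 0.469 with an estimated correlation. Scaled to snoRNAs, 1 ribosomal protein gene and 1 ribosome biogenesis gene were higher, and 9, 5 and 16 members of the other 3 lists lower. The medians of the first 2 lists were then 0.36 and 0.32, still above the protein-coding one, a position that scaling can hardly change. HXT13 (5.12 ± 0.45), STL1 (2.96 ± 0.26) and YLR264C-A (3.26 ± 1.09) had the largest differences upward, and BTN2, a chaperone-like protein sorting gene (-3.46 ± 0.22), GAC1 (-3.00 ± 0.30) and RGI1 (-2.91 ± 0.18) downward. Among lncRNAs they were CUT538 (3.90 ± 1.15), SUT067 (3.12 ± 0.80), NUT1459 (-2.88 ± 0.20), which kept a ratio of 0.748 to 0.755 to ATG41 in every library, and SUT068 (-2.80 ± 0.32). The XUT median was 0.15, or -0.13 and -0.28 under the other scalings. A lower response in xrn1 started from a higher level. In glucose, trehalose and glycogen, glucose-repressed sugar use and stress genes already had median changes of 2.72, 2.14 and 2.04 in xrn1. GAC1 and MAL11 were among the largest rises there. Among starved cells 5704 protein-coding genes stood higher and 11 lower in xrn1 than in wild type, a comparison added after the data were seen.

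Without Upf1, 569 features differed in their starvation response, 558 with a lower and 11 with a higher response than in wild type (294 higher and 690 lower when scaled to protein-coding genes). The limit from the solvent holds here too. The count ranged from 186 without replicate 1 of starved wild type to 1039 without replicate 2 of upf1 in glucose, was 124 when the fit held the compared groups alone, and reached 1822 when scaled to snoRNAs. The maltose permease genes MAL11 (-2.98 ± 0.23) and MAL31 (-2.85 ± 0.23), the mitochondrial carnitine carrier gene CRC1 (-1.92 ± 0.25), the glycogenin gene GLG1 (-1.86 ± 0.22) and the small ORF YGL258W-A (-2.37 ± 0.46) had a lower response in upf1. PHO84 (0.89 ± 0.21), the splicing factor gene CWC2 (0.89 ± 0.22) and HXT2 (0.62 ± 0.14) differed upward. CUT070 (2.39 ± 0.53) and CUT427 (2.18 ± 0.52) differed upward and CUT217 (-3.38 ± 0.81) and CUT120 (-2.79 ± 0.56) downward. Gluconeogenesis genes had 7 lower responses of 22 (0 and 11 adjusted over the list alone, camera adjusted p = 4.2e-04, adjusted p = 0.867 with an estimated correlation). In glucose 9 of them already stood higher and 2 lower in upf1 than in wild type. Among starved cells 3 stood higher and 5 lower (median -0.11). Of 1624 XUTs 1 had a higher and 133 a lower response, with a median of -0.46. With a pseudocount 10 times larger it was -0.20, against -0.12 for protein-coding genes. Of 830 SUTs 0 had a higher and 106 a lower response (-0.49). The protein-coding median was -0.15, and turned to 0.06 when scaled to protein-coding genes. Scaled to snoRNAs, 1 XUT was higher and 359 lower, with medians of -0.85 for XUTs and -0.70 for protein-coding genes. As deposited, camera gave adjusted p = 0.00250 for XUTs and 3.88e-08 for SUTs, and adjusted p = 0.409 and 0.360 with an estimated correlation. Among starved cells, upf1 still had 666 XUTs above and 8 below wild type (median 0.61), and xrn1 1590 above and 0 below (2.68). These comparisons within starvation were added after the data were seen.

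**Figure D3:**
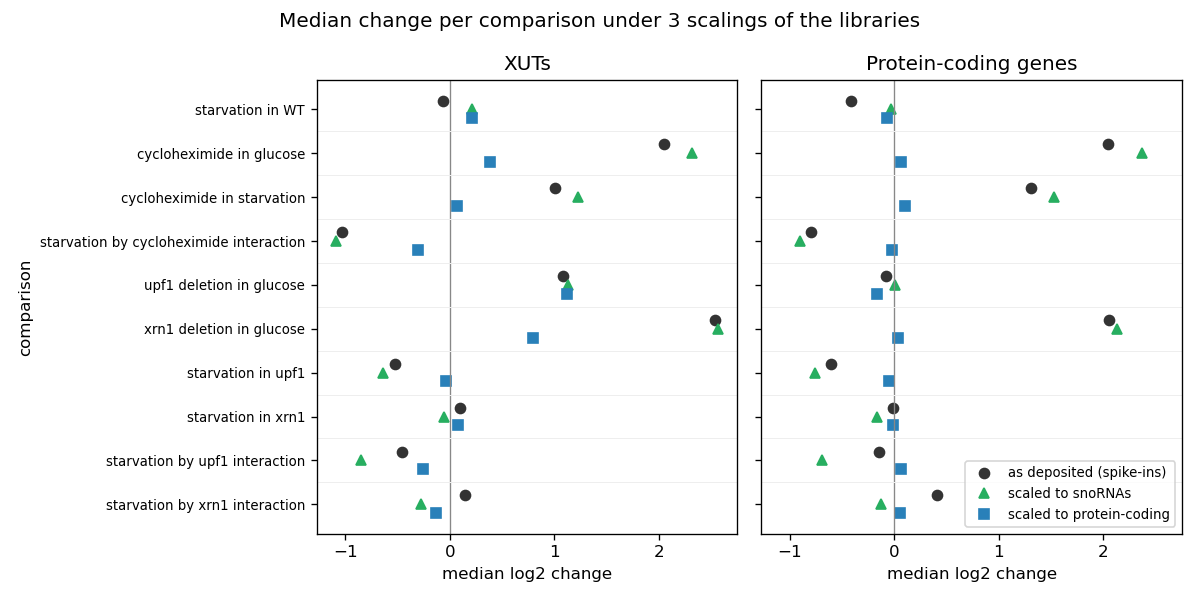
Median log2 change of XUTs (left) and protein-coding genes (right) in each planned comparison, as deposited and with libraries scaled to snoRNAs or to protein-coding genes. In upf1 in glucose the XUT median is 1.08, 1.13 and 1.12 under these scalings in that order, whereas with cycloheximide in glucose it is 2.05, 2.32 and 0.39.

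The overlap of XUTs called in the comparisons with wild type in glucose was tested by Fisher's exact test (both sides) over 1624 XUTs with Benjamini-Hochberg adjustment over 20 tests. XUTs that rose in upf1 also rose with cycloheximide in glucose in 1003 of 1011 cases, where independent lists would share 943 (odds ratio 25, exact p = 3.83e-36, adjusted p = 3.83e-35), and in xrn1 in 1008 cases against 980 (odds ratio 27.9, exact p = 2.22e-17, adjusted p = 1.48e-16). 1000 XUTs rose in all 3 comparisons and 566 rose in xrn1 and not in upf1. Of 182 XUTs that rose in starved wild type, 154 also rose in upf1 against 113 for independent lists (odds ratio 3.75, exact p = 3.92e-12, adjusted p = 1.96e-11). The overlap with cycloheximide in glucose (175 against 170, exact p = 0.116) and with xrn1 (180 against 176, exact p = 0.113) did not pass (adjusted p = 0.232 for both), but 1514 and 1574 of the 1624 XUTs rose there, which leaves little room for an excess. These comparisons share their control libraries. Unchanged groups simulated 50 times against them gave a Spearman correlation across XUTs of 0.470 and a covariance of 0.0520, and no baseline for the overlaps. The observed covariance was 0.377 between upf1 and cycloheximide, 0.425 between upf1 and xrn1, 0.325 between cycloheximide and xrn1 and 0.144, 0.151 and 0.0846 between starvation and upf1, xrn1 and cycloheximide. Correlations were 0.596, 0.618, 0.452, 0.306, 0.283 and 0.169. XUTs are not independent replicates. The correlation of cycloheximide with xrn1 and those of starvation lay below the simulated value. With separate controls, XUTs up with cycloheximide in starvation overlapped those up in upf1 in 761 cases against 627 (odds ratio 4.54, exact p = 4.14e-45, adjusted p = 8.28e-44, covariance 0.258) and those up in xrn1 in 997 against 976 (odds ratio 6.90, exact p = 8.95e-10, adjusted p = 3.58e-09). XUTs up with starvation in upf1 shared 25 with those up with cycloheximide in glucose, fewer than the 29.8 of independent lists (odds ratio 0.247, exact p = 0.00441, adjusted p = 0.0126), and 31 with those up in xrn1, as many as independent lists (31, odds ratio 0.984, exact p = 1).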

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

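The results here are mostly differences between groups in the response to the same treatment. Each feature counted for them passed a test of the interaction itself. Classes did not all pass (camera adjusted p = 0.704 for protein-coding genes with upf1, 0.281 for XUTs with cycloheximide), and none did with an estimated correlation. The labels name DMSO for wild type alone, so its effect cannot be told apart in the interactions with a deletion. The rises with cycloheximide and in xrn1, also treated here, are not interactions. All tests of explanations in this part were chosen after the results were seen, except those of the detection floor and of the Upf1-sensitive share of XUTs.

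The effect of cycloheximide differed between glucose and starvation for 7308 features, 239 higher and 7069 lower in starvation, with a protein-coding median of -0.80 and an XUT median of -1.03 (log2). Scaled to protein-coding genes, 1961 were higher and 2788 lower. Differences were OYE3 (6.08), YLR154C-H (5.03), RGI2 (3.22), SUT220 (3.21), CUT876 (3.07) upward and PCL1 (-4.39), YMR230W-A (-4.28), YMR141C (-4.26), CUT480 (-4.88), XUT0182 (-4.86) downward. The starvation response differed between upf1 and wild type for 569 features, 11 higher and 558 lower (protein-coding median -0.15, XUT median -0.46), or 294 higher and 690 lower scaled to protein-coding genes, with PHO84 (0.89), CWC2 (0.89), HXT2 (0.62), CUT070 (2.39), CUT427 (2.18) upward and MAL11 (-2.98), MAL31 (-2.85), YGL258W-A (-2.37), CUT217 (-3.38), CUT120 (-2.79) downward. It differed between xrn1 and wild type for 2751, 2358 higher and 393 lower (protein-coding median 0.40, XUT median 0.15). This direction rests on the scaling: 1499 were higher and 1596 lower scaled to protein-coding genes (medians 0.05 and -0.13), and 21 and 275 scaled to snoRNAs (medians -0.13 and -0.28). As deposited the largest were HXT13 (5.12), YLR264C-A (3.26), STL1 (2.96), CUT538 (3.90), SUT067 (3.12) upward and BTN2 (-3.46), GAC1 (-3.00), RGI1 (-2.91), NUT1459 (-2.88), SUT068 (-2.80) downward. A lower response need not mean a lower level in starved xrn1, since most transcripts already stood higher in xrn1 in glucose.

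Most transcripts stood higher with cycloheximide in glucose. Less sample per spike-in in the mock libraries, or less ribosomal RNA per cell with the drug, would raise every other RNA alike, but the median of 76 snoRNAs changed by -0.302 (SD 0.447) and that of 25 mitochondrially encoded features by -0.21 (SD 0.545), where the protein-coding median changed by 2.05. Background reads would add the same coverage to every gene, but the fifth abundance decile gained 0.742 reads per nucleotide and the lowest 0.0659. A prefix difference as cause of the rise in glucose and in starvation cannot be told apart from the drug, since 0 of the 4 libraries with that prefix lack it, so a biological rise remains a hypothesis that may or may not hold.

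Most transcripts also stood higher in xrn1. The median of 76 snoRNAs changed by -0.0542 (SD 0.420) and that of 25 mitochondrially encoded features by 0.89 (SD 0.363), against 2.06 for protein-coding genes, which argues against less sample per spike-in in wild type and against less ribosomal RNA per cell in xrn1 with other RNAs raised alike, as the whole cause. The fifth abundance decile gained 0.746 reads per nucleotide and the lowest 0.0479, which argues against background. The solvent named for wild type alone would act on upf1 as well, whose protein-coding median changed by -0.0837. Slower decay of mRNAs without the exonuclease is a candidate explanation that the design names and that was not tested here.

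The response of XUTs to starvation was lower in upf1 (median -0.52) than in wild type (-0.07). Of 1624 XUTs 133 passed as lower (camera adjusted p = 0.00250, or 0.409 with an estimated correlation). Protein-coding medians were -0.61 and -0.42, so XUTs fell no more than mRNAs in upf1 and lay 0.35 above them in wild type. Values near the detection floor in wild type would hide a fall. The 153 XUTs at or above 10 times the pseudocount there had an interaction median of -0.632 against -0.152 for protein-coding genes. Their choice used the mean of both wild-type groups, which also enter the interaction. XUTs high in starved wild type alone could pass, so these values cannot exclude the floor. These 153 changed by 0.24 in wild type and by -0.32 in upf1, so much of their difference is a rise in wild type. A pseudocount 10 times larger, above the level of most XUTs, brought the median of all XUTs from -0.46 to -0.20 against -0.12 for protein-coding genes, and that of these 153 to -0.45. A scaling error in 1 group would move protein-coding genes as well. Relative to them the interaction median of the 153 XUTs lay at -0.480 as deposited, -0.506 scaled to protein-coding genes and -0.473 scaled to snoRNAs. The value nearest 0 with 1 library left out was -0.377. At these levels a scaling error would move XUTs and mRNAs alike, so the values argue against it as the cause of this gap. The choice of these XUTs used the wild-type groups compared here, so the gap itself may be biased by that choice. For the other 1471 XUTs the same values were -0.293, -0.298 and -0.123 (nearest 0, -0.0395), so a scaling error stays open for them. The difference between the XUT and protein-coding medians of each library gave an interaction of -0.138 with an SE of 0.0764, too close to 0 to decide alone. The interaction differed by -0.378 between the 541 XUTs with the highest mean Upf1 effect and the 542 with the lowest (-0.222 there). Starvation changed these 541 and 542 XUTs by -0.622 and -0.352 in upf1, and by -0.0427 and -0.117 in wild type. The difference thus lay mostly in upf1, where the 541 fell about as much as protein-coding genes (-0.61). Loss of the Upf1-sensitive share of XUT signal in starvation may contribute. These values do not tell it apart from a fall in upf1 like that of mRNAs.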

How the results depend on the processing

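Directions and calls of the named features mostly held: of 503 pairs of feature and comparison, 503 kept direction and call when scaled to spike-ins, 502 without a filter, 499 with a replicate block, 489 and 481 with a smaller and larger pseudocount, 487 with the compared groups only, 467 and 446 when scaled to protein-coding genes and to snoRNAs, and 434 with a 2-fold minimum. In the fit without the 4 cycloheximide libraries, chosen after seeing the data, 325 of 327 held. Scaling to spike-ins had factors of 1.00, so it could not change a call. With each library left out in turn no direction reversed, though some calls were lost. Outside the interactions the largest changes were chosen with both libraries of 1 group above both of the other. Their direction could therefore not reverse when 1 library was left out. All named features were also chosen for passing in these same data. The planned count test (edgeR) was not run, since reads were whole for only 49.7 to 80.1% of the low-count ORFs checked. Except where a setting's own construction gives it, the cause was not tested.

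With a 2-fold minimum, which passes fewer by construction, counts were 1430 against 5047 for starvation in wild type, 4731 against 7308 for its interaction with cycloheximide, 2399 against 4873 for upf1, 1459 against 6389 for starvation in upf1, 165 against 352 for starvation in xrn1, and 357 against 569 and 703 against 2751 for the interactions with upf1 and xrn1. With an estimated correlation, passing classes numbered 0 against 6 for starvation in wild type, 3 against 6 for cycloheximide in starvation, 0 against 4 for the cycloheximide interaction, 0 against 7 for upf1, 4 against 7 for xrn1, 0 against 7 and 0 against 4 for starvation in upf1 and xrn1, and 0 against 6 and 0 against 5 for their interactions. Passing lists numbered 0 against 13, 14, 14 and 12 for starvation in wild type, cycloheximide in glucose, in starvation and their interaction, 0 against 16 and 10 for upf1 and xrn1, 1 against 11 and 1 against 12 for starvation in them, and 0 against 11 and 15 for the interactions.

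With the compared groups only, 1049 features passed for starvation in xrn1 and 124 for the upf1 interaction. Over 28 pairs of groups the replicate differences correlated at -0.0863 to 0.0816. That check removes shifts shared by a whole library, so whether the replicate numbers pair the libraries stays open. With the replicate number as a block the counts were 554 and 956. With a pseudocount 10 times larger they were 561 and 348, and XUT medians were 0.96 and 0.36 for cycloheximide in glucose and starvation, -0.51 for their interaction, 0.39 for upf1, 1.28 for xrn1, -0.22 for starvation in upf1 and -0.20 for its interaction. With one 10 times smaller they were 2.45, 1.28, -1.13, 1.40, 2.99 and -0.62 for the first 6 of these. The stricter filter gave 2.28 and 1.30 for cycloheximide, 1.32 for upf1 and 2.92 for xrn1.

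Scaled to protein-coding genes, counts were 6594 for cycloheximide in glucose, 4749 for its interaction, 4128 and 999 for starvation in upf1 and xrn1, and 984 for the upf1 interaction. XUT medians were 0.21 for starvation in wild type, 0.39, 0.0664 and -0.31 for cycloheximide in glucose, in starvation and their interaction, 0.79 for xrn1, -0.0405 for starvation in upf1, and -0.26 and -0.13 for the interactions with upf1 and xrn1. Directions reversed for PFK2 (-1.04) and PFK1 (-1.14) with cycloheximide in glucose, HTB1 (0.10), HTA1 (0.25) and AFB1 (0.16) in the cycloheximide interaction, and GCD7 (-0.22), GPM1 (-0.98), FBA1 (-1.20), HTB1 (-0.28), HHF2 (-0.31) and PHM8 (-0.47) in xrn1. Scaled to snoRNAs, counts were 1940 for starvation in wild type, 122 in xrn1, and 1822 and 296 for the interactions; XUT medians were 0.21, 2.32 and 1.23 for starvation and the 2 cycloheximide effects, -0.64 and -0.055 for starvation in upf1 and xrn1, and -0.85 and -0.28 for the interactions.

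Leaving out each replicate in turn gave 139 to 198 features for starvation in xrn1, 186 (without starved wild type replicate 1) to 1039 (without upf1 glucose replicate 2) for the upf1 interaction, and 1661 to 2446 for the xrn1 interaction. XUT medians ranged over 1.99 to 2.17 for cycloheximide in glucose, 1.01 to 1.17 for upf1 and -0.61 to -0.44 for starvation in upf1. The lone library of a group is assumed there to vary like the other groups. Depth limits low features most: the pseudocount equals 3.29 to 13.8 reads per kb.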

Other observations

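The rise of mRNAs without Xrn1 and with cycloheximide differed with their level. The middle protein-coding genes, the fifth decile by level, had median log2 changes of 2.26 in xrn1 and 2.25 with cycloheximide in glucose, and the highest decile 1.07 and 1.11. In the lowest decile they were 1.89 and 2.24, so the change was not a steady one in xrn1. With cycloheximide in starvation the fifth and highest lay at 1.5 and -0.16. The gene lists were not matched for level, so their relative medians in these comparisons may partly reflect it.

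The test of these sizes was chosen after the values were seen; that of XUTs in starved wild type was written before. Across 5817 protein-coding genes, which are not independent replicates, the effect of xrn1 correlated with that of cycloheximide in starvation, which has other controls, at a Spearman coefficient of 0.594. A shared dependence on decay may link these effects, though level alone could also do so.

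If nonsense-mediated decay weakened in starved wild type, XUTs more sensitive to Upf1 would rise more there. With the Upf1 effect taken against 1 control library and the starvation effect against the other, the Spearman coefficients across 1624 XUTs were 0.146 and 0.179, with a mean of 0.162, between the bounds set for and against, so the hypothesis may hold or not and stays open.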
